A study of Arabidopsis thaliana with 8 samples.

How the data were processed

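RNA was measured by short-read sequencing in inflorescences of Arabidopsis thaliana that held flowers of stage 8 and younger. The 8 libraries came from 4 genotypes, the Landsberg erecta wild type (Ler), ag-10, fhy3-68 and ag-10 fhy3-68, with 2 libraries each, which the series describes as biological replicates. Genotype and replicate number were taken from the library titles.

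The deposited values are a normalised signal per gene and library: gene read counts divided by a size factor of the library and put on a scale of reads per 1000000. This unit was worked out from the values. Within a library each value was a whole multiple of what 1 read is worth, rounded to 2 decimals, and after division by that step 100% of the values lay within 0.1 of a whole read. The column totals lay between 974821.7 and 1037312.39, on both sides of 1000000, as division by an effective library size gives. CASAVA 1.8, TopHat2 2.0.14, HTSeq 0.6.1p1 and edgeR 3.10.0 are named without a role or order, per the submitters' processing notes. The genome build, the annotation, the counting mode and the use of strand are not given in the sources used here. The deposited table held 19853 genes, each with a value of at least 1 in at least 2 libraries, so a gene below that level everywhere was not analysed here. It held 0 organelle genes. The genes AG and CLV3, both in the lists below, were not analysed here.

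The recovered reads in the listed genes came to 14055142 and 12322061 in the Ler libraries, 14029288 and 12727551 in ag-10, 14836412 and 14091808 in fhy3-68, and 14780718 and 16816619 in ag-10 fhy3-68. In the deposited unit 1 read was worth between 0.0598 and 0.0793. Intervals on ratios of low counts are exact binomial intervals at 95%. Reads from PCR without molecular identifiers are not independent molecules, so these intervals and the floor below cover counting error only. Where a genotype had 0 reads in both libraries, the fold was computed against a floor of 3 reads over the genotype. Gene names came from the RefSeq annotation of TAIR10.1, which matched 19811 of the 19853 gene identifiers (99.79%) and was used for names and neighbour order only. Among the 62 genes named by the rule below, 9 overlap another gene model there, and reads of the 2 models may not have been told apart: AT3G47010, AUR1, LKP2, ALDH3H1, CRC, CAO, SPL15, AT5G39520 and AT3G15450. Some symbols name more than 1 gene in the reference: FHY1 stands here for AT2G37678, FAR1 for AT4G15090, SEP2 for AT3G02310, CAO for AT1G44446, MS2 for AT3G11980, HB21 for AT2G18550 and SEN1 for AT4G35770.

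The samples, contrasts, tests, gene lists, naming rule and alternatives called planned below were fixed before the data were examined. The planned test was the quasi-likelihood test of edgeR on counts. Because the values were already normalised, the main test was instead limma (version 3.58.1, R 4.3.3) with an intensity trend on log2(value + 0.5), with a coefficient per genotype over all 8 libraries, 4 residual degrees of freedom and 3.41 prior degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Fold changes are therefore on the log2(value + 0.5) scale, which understates the change of low genes. The contrasts were ag-10, fhy3-68 and ag-10 fhy3-68 against Ler, ag-10 fhy3-68 against each of its parents, and the interaction, which is the effect of fhy3-68 in the ag-10 background minus its effect in Ler. The edgeR quasi-likelihood test (version 4.0.16) on the recovered reads was run as an added alternative.

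The 21 planned gene lists had 353 entries: study genes, floral organ identity, meristem, carpel and ovule, anther and tapetum, light signalling, circadian clock, photosynthesis, chlorophyll synthesis, salicylic acid defence, jasmonate, auxin response, cytokinin response, cell division, flavonoids, heat shock, rapid stress, mature pollen, late flower and nectary, seed, and flowering time. The lists of rapid stress and heat shock genes were meant as signs of handling and growth conditions, and those of mature pollen, late flowers and seeds as signs of older tissue. Of the entries, 4 were dropped because the reference gives their identifier another name, and 44 were not analysed here. The seed list kept 0 members. The late flower list kept 2 members, under the minimum of 5 for a test. The other 19 lists were tested with limma's camera on log2(value + 0.5) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 19 lists within a contrast. Camera was also run with an estimated correlation per list, and fry, which tests whether the genes of a list move on balance one way, was run beside it. The mixed test of fry, which asks whether the genes of a list change in either direction, was also run. It does not compare a list with the other genes. The same genes were also counted with adjustment over the list alone.

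Genes were named by a planned rule. For each contrast it takes up to 10 called genes with the largest increase and 10 with the largest decrease (5 and 5 for ag-10 fhy3-68 against fhy3-68 and for the interaction), among genes with a mean of at least 2 over the 8 libraries and with no overlap between the libraries of the genotypes compared, a condition not used for the interaction. It adds every study gene and up to 4 called members of each list with the smallest adjusted p. Members of the lists that were not called may be named with their values.

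The alternatives planned were median-ratio (RLE) size factors, library totals alone, a minimum of 1 in at least 2 libraries, DESeq2 (version 1.42.0) and the exact test of edgeR on the recovered reads, a fit on the 4 libraries compared, a minimum absolute log2 fold change of 1, the replicate number as a block, and leaving out each library in turn. Added after the data were seen were the edgeR quasi-likelihood test, pseudocounts of 0.1 and 1, a minimum mean of 5, a crossed block, the overlap of the fhy3-68 comparisons fitted each on its own 4 libraries, and 4 further lists: dark and sugar starvation, senescence and dormancy, and morning and evening clock genes. For contrasts that share the Ler libraries, 100 sets of unchanged libraries were simulated. Replicate libraries of a genotype differed by more than sampling noise, with a chi-square per degree of freedom of 4.73 in Ler, 12.3 in ag-10, 27.6 in fhy3-68 and 12.2 in ag-10 fhy3-68, so no pair looked like 1 library deposited again. They were counted as separate samples because the series describes them as biological replicates.

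The limma procedure was tested on simulated data for the comparison of fhy3-68 with Ler over 19853 genes, with 50 genes changed at each fold size. Apart from these changes, every genotype was given the same mean and dispersion per gene. The measured replicate spread differed between Ler and fhy3-68, so the shares recovered may not hold for the measured comparison. The procedure recovered 4% of the genes changed 1.5-fold, 56% of those changed 2-fold, 90% of those changed 4-fold and 90% of those changed 8-fold. It called 13 unchanged genes, beside 2, 28, 45 and 45 changed genes in the order of these folds. Camera called the list of changed genes and 0 of 20 random lists. The simulated genes were drawn independently of each other. These lists therefore do not test camera on genes that move together, and the estimated correlation of the measured rapid stress list was 0.798.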

Results

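Transcript levels were measured in young inflorescences of the Ler wild type, of the ag-10 mutant, of the fhy3-68 mutant and of the ag-10 fhy3-68 double mutant, with 2 libraries per genotype. FHY3 is a transcription factor derived from a transposase that acts in phytochrome A signalling, and AGAMOUS (AG) specifies stamens and carpels and ends floral meristem activity. The labels tie the series to a search for FHY3 binding sites in flowers, so the comparisons ask which transcripts depend on FHY3 and on AG and whether the effect of each mutation depends on the other. The values are normalised read counts on a scale of 1000000 reads per library. Between 12322061 and 16816619 reads of a library fell in the 19853 listed genes. On the first principal component, which held 60.7% of the variance, the Ler libraries lay at -39.44 and -38.26 and the fhy3-68 and ag-10 fhy3-68 libraries between 22.63 and 48.75. The ag-10 libraries lay apart from each other, at -44.26 for replicate 1 and -17.94 for replicate 2.

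The genes under study were examined first. AG was not analysed here. FHY3 mRNA stood at 107 ± 4.55 in Ler, 104 ± 0.148 in ag-10, 81.7 ± 15.9 in fhy3-68 and 88.8 ± 4.18 in ag-10 fhy3-68 (SD, n = 2 each). Its log2 fold change of -0.39 (SE 0.13) in fhy3-68 did not pass the test (limma, Benjamini-Hochberg adjusted p = 0.125), but did without fhy3-68 replicate 2 (-0.59, limma adjusted p = 0.048). The labels do not give the lesion of fhy3-68, so the transcript level does not check the genotype. FAR1, the closest homologue of FHY3, rose from 43.1 ± 0.785 in Ler to 58.4 ± 3.34 in fhy3-68 and 65.9 ± 0.177 in ag-10 fhy3-68. Its log2 fold changes were 0.43 (SE 0.08, limma adjusted p = 0.0407) in fhy3-68 and 0.61 (SE 0.08, limma adjusted p = 0.0199) in the double mutant, and 0.54 (SE 0.08, limma adjusted p = 0.0353) for the double mutant against ag-10.

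SEP2, a MADS-box gene of organ identity, stood at 233 ± 18 in Ler and 158 ± 3.39 in fhy3-68, a log2 fold change of -0.56 (SE 0.13, limma adjusted p = 0.0594) that missed the threshold. In the double mutant it was 183 ± 24.9, with a log2 fold change of -0.35 (SE 0.13, limma adjusted p = 0.146) against Ler and -0.48 (SE 0.13, limma adjusted p = 0.102) against ag-10. DESeq2 called SEP2 in fhy3-68 against Ler (adjusted p = 0.00387) and in the double mutant against ag-10 (0.0282). Limma with the replicate number as a block called it in fhy3-68 against Ler (limma adjusted p = 0.0406). WUS, the homeodomain gene that maintains stem cells, stood at 12 ± 0.148 in Ler, 11 ± 1.17 in ag-10, 9.14 ± 0.912 in fhy3-68 and 7.5 ± 0.728 in the double mutant. Its log2 fold change of -0.64 (SE 0.15) in the double mutant against Ler also missed the threshold (limma adjusted p = 0.0556). With the replicate number as a block, WUS was called there (limma adjusted p = 0.0325). Replicate numbers of Ler did not pair with those of the mutants (correlations of 0.02, 0.07 and -0.11). The block therefore lends little weight to the calls of SEP2 and WUS against Ler. With the Ler numbers crossed, the count for the double mutant against Ler still rose, from 859 to 1488 genes. Leaving out either fhy3-68 library, which this comparison does not hold, kept the fold at -0.64. It moved the test of WUS through the variance shared by all genotypes. KNU, which encodes a zinc finger repressor of WUS, rested on 25 to 40 reads per genotype and was not called in any contrast (double mutant against Ler 0.06, SE 0.3, limma adjusted p = 0.922). Adjusted over the list alone, FAR1 was higher and 3 of the 5 measured study genes were lower in fhy3-68, and 2 were lower in the double mutant. Camera did not call the list in any contrast, with adjusted p from 0.266 to 0.78. The mixed test of fry, which allows opposite directions, gave it an unadjusted p = 6.96e-05 in fhy3-68 against Ler.

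**Figure D1:**
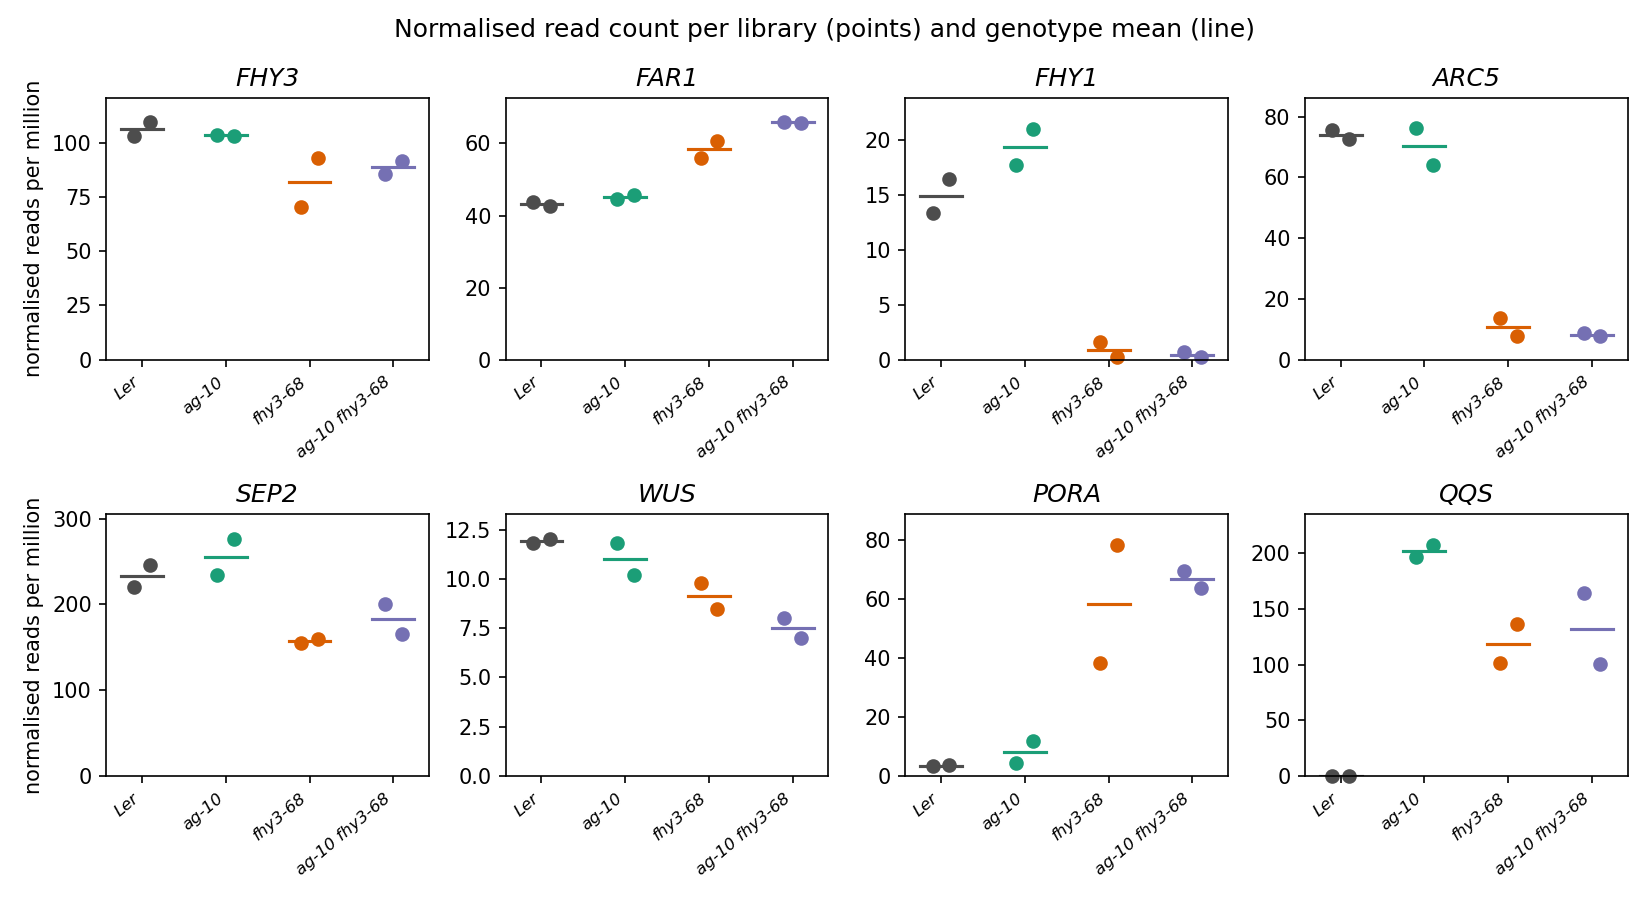
Normalised read count (scaled to 1000000 reads) of 8 genes in each of the 8 libraries (points) with the genotype mean (line), on linear axes that start at 0. FHY1 and ARC5 are lower in the fhy3-68 and ag-10 fhy3-68 libraries, PORA is higher in those libraries, and QQS is near 0 in Ler alone.

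In ag-10 inflorescences, 1 gene was called against Ler. That gene was QQS (AT3G30720), an orphan gene known to affect starch content. QQS stood at 0.23 ± 0.127 in Ler and 202 ± 7.61 in ag-10 (SD, n = 2 each), from 6 and 5490 reads, which is a ratio of 897 with a counting interval of 412 to 2450. Its log2 fold change was 8.12 (SE 0.25, limma adjusted p = 5.42e-05), and both ag-10 libraries lay above both Ler libraries.

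The anther and tapetum list, which holds genes for sporogenous tissue and pollen wall precursors, was lower in ag-10 in 21 of 23 members, with 0 members called and 0 adjusted over the list alone. Its median log2 fold change was -0.22 (camera adjusted p = 2.84e-06, and adjusted p = 0.934 with an estimated correlation). The salicylic acid list was higher in 19 of 21 members, with a median of 0.29, also with DLO1 (0 reads in Ler) at its bound, and 0 members called (camera adjusted p = 3.52e-05, and adjusted p = 0.934 with an estimated correlation). Its members PR2 and PR5, which encode pathogenesis-related proteins, stood at 3.81 and 6.28 in ag-10 replicate 1 and at 49.86 and 70.23 in replicate 2, against at most 1.21 and 3.17 in Ler. Without ag-10 replicate 2 the list was no longer called (camera adjusted p = 0.666). Heat shock genes had a median of -0.28 (camera adjusted p = 0.048, and adjusted p = 0.934 with an estimated correlation). That call was lost without Ler replicate 1 (camera adjusted p = 0.82, with the opposite direction), without ag-10 replicate 1 (0.64) and without either fhy3-68 library (0.0517). The carpel and ovule list had 1 member lower when adjusted over the list alone and 0 over all genes. The other 16 tested lists had camera adjusted p from 0.332 to 0.966. The 2 measured late flower genes, CWINV4 and TPS11 (AT5G44630), had a median of -0.27 and were not called.

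At an unadjusted p under 0.05, limma found 357 genes in this comparison. The edgeR quasi-likelihood test also called 1 gene, DESeq2 called 23 and the exact test of edgeR called 27. Without ag-10 replicate 1, limma called 4 genes, where the remaining ag-10 library was assumed to vary like the other genotypes.

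The comparison of fhy3-68 with Ler asks which transcripts depend on FHY3. FHY1 (AT2G37678), which carries phytochrome A into the nucleus, fell from 14.9 ± 2.23 in Ler to 0.915 ± 0.983 in fhy3-68 (SD, n = 2 each). ARC5, a dynamin-related protein of chloroplast division, fell from 74.1 ± 1.89 to 10.8 ± 4.19. PORA, which encodes a protochlorophyllide oxidoreductase, rose from 3.46 ± 0.382 to 58.3 ± 28.2. In all, 605 genes were called, 449 higher and 156 lower.

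Among the largest decreases, the log2 fold change was -3.64 for FHY1 (SE 0.48, limma adjusted p = 0.025) and -2.77 for ARC5 (SE 0.23, limma adjusted p = 0.0134). FHY1 rested on 26 reads in fhy3-68 and 396 in Ler, a ratio of 16.1 with a counting interval of 10.8 to 24.9. The others were AT3G57930 (-3.74), AT2G41990 (-3.23), AT2G40820 (-2.44), AT3G47010 (-2.31), the B-box gene BBX31 (-2.14), AT1G11700 (-2.13), the starch debranching enzyme gene DBE1 (-2.09) and the arogenate dehydratase gene ADT4 (-2.07). Their limma adjusted p lay between 0.0137 and 0.0361.

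The largest increase was that of QQS, at 119 ± 24.9 in fhy3-68 and 0.23 ± 0.127 in Ler, with a log2 fold change of 7.35 (SE 0.25, limma adjusted p = 0.000114). BT2, which encodes a scaffold protein with BTB and TAZ domains, rose by 5.9 (SE 0.98, limma adjusted p = 0.0352), from 4 reads in Ler to 1721, and its fhy3-68 libraries stood far apart at 13 and 110.58. AT2G33830, of the dormancy and auxin associated family, rose by 5.47 (SE 1.1, limma adjusted p = 0.0487) and stood at 43.07 and 323.87 in the 2 fhy3-68 libraries. The other large increases were AT1G12010 (5.39), AT2G05540 (5.3), the calmodulin-binding regulator of salicylic acid synthesis CBP60G (4.37), AT3G50625 (4.11), the cysteine endopeptidase gene CEP1 (4.07), the NAC domain gene NAC3 (4.02) and MEE14 (3.97), with limma adjusted p from 0.0134 to 0.0464. CEP1 rested on 1 read in Ler and 254 in fhy3-68, a ratio of 241 with a counting interval of 42.8 to 9540.

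Camera called the rapid stress, jasmonate and salicylic acid lists as higher in fhy3-68, but not with an estimated correlation (adjusted p = 0.478 for each). All 14 rapid stress genes, which respond to touch, wounding and cold, lay higher, with a median log2 fold change of 2.3, and 1 was called (12 higher adjusted over the list alone). The called gene was the calmodulin-like gene CML38 (2.94, SE 0.48, limma adjusted p = 0.0352), while the cell wall gene TCH4 stood at 44.7 ± 33.5 in Ler and 413 ± 64.1 in fhy3-68. Camera called this list (adjusted p = 7.68e-07, and adjusted p = 0.478 with an estimated correlation). The per-library median of the list, relative to the mean of all 8 libraries, was -0.6 and -1.59 in Ler, -2 and -0.14 in ag-10, 1.34 and 1.38 in fhy3-68, and 0.42 and 1.13 in the double mutant.

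Jasmonate genes had 2 members called higher, 0 lower and 18 not called, and 12 higher adjusted over the list alone. The called members were LOX4, a lipoxygenase gene (2.51, SE 0.49, limma adjusted p = 0.0448), and the repressor gene JAZ9 (0.8, SE 0.15, limma adjusted p = 0.0447). The list had a median of 1.13 (camera adjusted p = 2.73e-06, and adjusted p = 0.478 with an estimated correlation). Salicylic acid genes had 2 members called higher, CBP60G and the lipase-like gene SAG101 (1.04, SE 0.2, limma adjusted p = 0.0423), 19 not called, and 12 higher adjusted over the list alone, with a median of 1.37, also with DLO1 at its bound (camera adjusted p = 2.32e-06, and adjusted p = 0.478 with an estimated correlation). Auxin response genes had 2 of 9 called higher and 4 adjusted over the list alone. These were the early auxin gene IAA2 (1.71, SE 0.15, limma adjusted p = 0.0134) and the auxin-conjugating enzyme gene GH3.5 (1.6, SE 0.27, limma adjusted p = 0.0352). The auxin list had a median of 0.48 (camera adjusted p = 0.00403, and adjusted p = 0.478 with an estimated correlation), and its call was lost without fhy3-68 replicate 1. Its estimated correlation of -0.006 lay under the preset 0.01, yet its unadjusted camera p went from 0.00148 to 0.0299. That loss was therefore not due to a correlation above the preset one.

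Of the 22 photosynthesis genes, 21 lay higher, by a median of 0.32, with 0 called and 6 adjusted over the list alone (camera adjusted p = 6.64e-06, and adjusted p = 0.479 with an estimated correlation). Chlorophyll synthesis genes had 2 called higher, PORA (3.81, SE 0.45, limma adjusted p = 0.0199) and the glutamyl-tRNA reductase gene HEMA1 (0.55, SE 0.09, limma adjusted p = 0.0352), and 5 adjusted over the list alone, but camera did not call the list (median 0.05, adjusted p = 0.0921). Clock genes had a median of 0.51, with LKP2, which encodes an F-box photoreceptor, called higher (0.61, SE 0.11, limma adjusted p = 0.0406). Adjusted over the list alone, 10 of the 27 were higher and 1 lower (camera adjusted p = 0.00407, and adjusted p = 0.478 with an estimated correlation). In the light signalling list, FAR1 and PIF5, a bHLH gene that promotes growth in shade (0.85, SE 0.14, limma adjusted p = 0.0346), were higher and FHY1 was lower. Adjusted over the list alone, 4 were higher and 3 lower, and camera did not call the list (adjusted p = 0.983).

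Camera called anther and cell division genes as lower in fhy3-68, but not with an estimated correlation (adjusted p = 0.478 for both). Of 23 anther and tapetum genes, 21 lay lower, with a list median of -0.49, with the sporopollenin gene CYP703A2 called (-0.81, SE 0.14, limma adjusted p = 0.0354) and 10 lower adjusted over the list alone (camera adjusted p = 2.73e-06, and adjusted p = 0.478 with an estimated correlation). All 15 cell division genes lay lower, with a median of -0.45. The Aurora kinase gene AUR1 was called (-0.52, SE 0.09, limma adjusted p = 0.0365) and 11 were lower adjusted over the list alone (camera adjusted p = 7.05e-07, and adjusted p = 0.478 with an estimated correlation). The 25 meristem genes had a median of -0.06 and 0 called (camera adjusted p = 0.109), but the mixed test of fry gave an unadjusted p = 0.000319. In the floral organ identity list, FUL, a MADS-box gene of fruit and meristem identity, was higher (0.56, SE 0.09, limma adjusted p = 0.0347), and adjusted over the list alone 3 were higher and 3 lower (camera adjusted p = 0.666). In the carpel and ovule list, SPT, a bHLH gene of carpel margins, was lower (-0.66, SE 0.09, limma adjusted p = 0.0287; camera adjusted p = 0.666). Camera did not call the cytokinin (0.666), flavonoid (0.0921), heat shock (0.262), flowering time (0.983) and mature pollen (0.364) lists, given here as adjusted p. With adjustment over the list alone, 2 flowering time genes and 1 pollen gene were higher, and 1 flowering time, 2 heat shock and 1 carpel gene were lower. The late flower genes had a median of 0.07. Pollen markers stood unevenly between replicates: VGD1, a pollen tube pectin methylesterase gene, was at 63.69 and 19.09 in fhy3-68 and 6.39 and 22.38 in Ler.

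**Figure D2:**
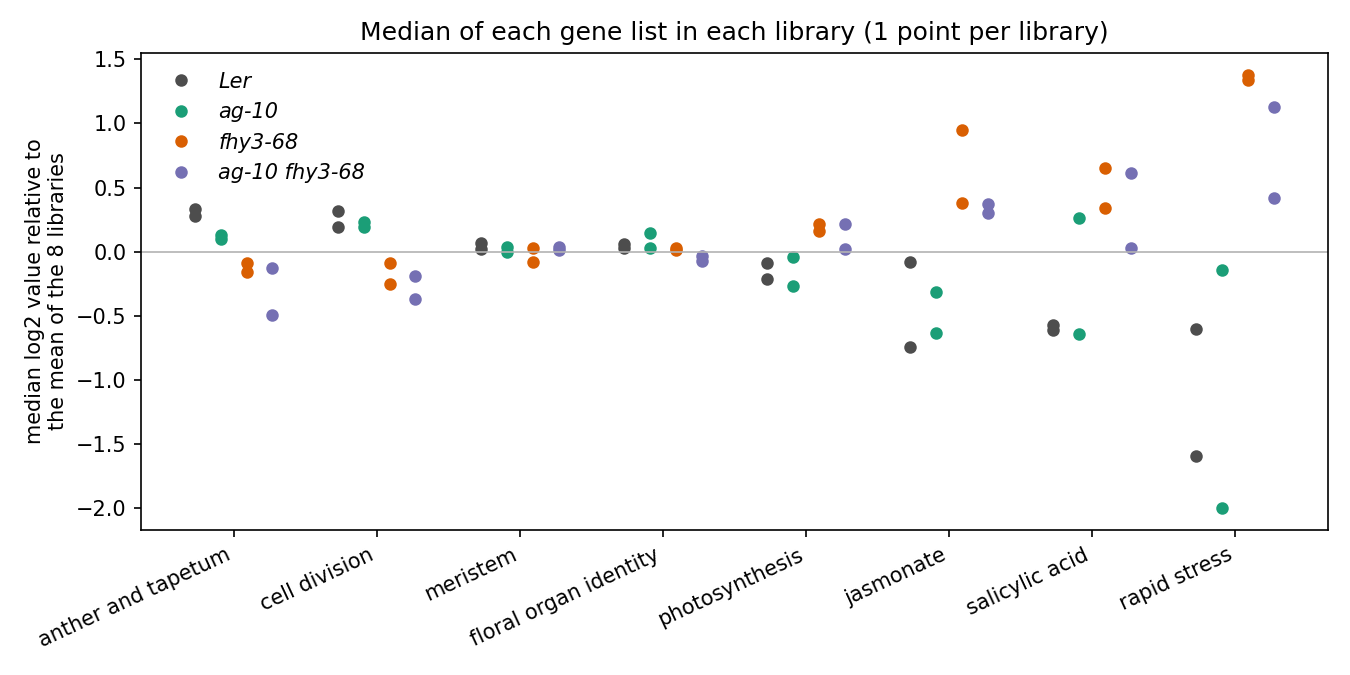
Median log2 value of 8 gene lists in each of the 8 libraries, relative to the mean of the 8 libraries (1 point per library, colour for genotype). The rapid stress medians run from -2 in ag-10 replicate 1 to 1.38 in fhy3-68 replicate 2, and the meristem medians lie near 0 in all 4 genotypes.

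With library totals in place of the size factors, 674 genes were called, 376 higher and 298 lower, so the share called higher went from 74.2% to 55.8%. On the 4 libraries compared the share went the other way, to 91.9%, with 345 genes called, 317 higher and 28 lower. The edgeR quasi-likelihood test did not call BT2 (adjusted p = 0.0512), AT2G33830 (0.054), MEE14 (0.0513) and LOX4 (0.0506), and DESeq2 did not call LKP2 (0.0519). In fits without 1 library, the remaining library of that genotype was assumed to vary like the other genotypes. Replicates differed most in fhy3-68 (chi-square per degree of freedom 27.6) and least in Ler (4.73), so a high count without a fhy3-68 library does not show more changed genes. The limma count was 1 without Ler replicate 1 and 1 without Ler replicate 2, 3399 without fhy3-68 replicate 1, 131 without fhy3-68 replicate 2, and 285 and 287 without ag-10 fhy3-68 replicates 1 and 2.

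The double mutant was also compared with Ler. FHY1 fell to 0.46 ± 0.311 and ARC5 to 8.18 ± 0.742 in ag-10 fhy3-68 (SD, n = 2 each), while PORA rose to 66.6 ± 3.97. In total 859 genes were called, 492 higher and 367 lower.

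Decreases were led by AT3G57930 (-4.59, SE 0.61, limma adjusted p = 0.0201), FHY1 (-4.04, SE 0.48, limma adjusted p = 0.0164), AT2G41990 (-3.64, SE 0.31, limma adjusted p = 0.00755) and ARC5 (-3.11, SE 0.23, limma adjusted p = 0.00747). Next were AT3G47010 (-2.87), AT2G40820 (-2.56), ADT4 (-2.44), AT5G11930 (-2.33), AT3G07580 (-2.21) and the aldehyde dehydrogenase gene ALDH3H1 (-2.17), with limma adjusted p from 0.00755 to 0.0291. Increases were led by QQS (7.48, SE 0.25, limma adjusted p = 1e-04), at 132 ± 45.3. They included AT2G05540 (5.95), AT1G12010 (5.88), CEP1 (5.73), AT2G33830 (5.72), BT2 (5.68), AT3G50625 (5.3), CEP2, a second cysteine endopeptidase gene, CBP60G (4.56) and SEN1, a gene induced in the dark (4.72), with limma adjusted p from 0.00747 to 0.0444. CEP2 had 0 reads in Ler and 639 in the double mutant and was at least 181-fold higher.

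Of the 23 anther and tapetum genes, 9 were lower in the double mutant and 14 were not called. The lowest adjusted p were those of the tapetum gene A9 (-0.89, SE 0.1, limma adjusted p = 0.0148), CYP703A2 (-1.17, SE 0.14, limma adjusted p = 0.0164), SPL, which starts sporogenous tissue (-0.88, SE 0.12, limma adjusted p = 0.0219), and the pollen wall gene MS2 (-1.15, SE 0.16, limma adjusted p = 0.0234). Adjusted over the list alone, 15 were lower and 1 higher, and the median was -0.61 (camera adjusted p = 6.89e-09, and adjusted p = 0.505 with an estimated correlation). Relative to the mean of the 8 libraries, the anther median in replicates 1 and 2 was -0.49 and -0.13 in ag-10 fhy3-68. It was -0.16 and -0.09 in fhy3-68, and 0 members were called between these 2 genotypes. The larger number called here therefore does not show a stronger decrease than in fhy3-68. Of 15 cell division genes, 5 were lower, among them AUR1 (-0.79), CYCB3;1 (-0.64), CYCB1;2 (-0.62) and CYCB1;1 (-0.57), and 14 were lower adjusted over the list alone. That list had a median of -0.51 (camera adjusted p = 1.24e-08, and adjusted p = 0.505 with an estimated correlation).

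In the double mutant, 3 chlorophyll synthesis genes were higher, PORA (4.08, SE 0.45, limma adjusted p = 0.0148), HEMA1 (0.5, SE 0.09, limma adjusted p = 0.0371) and the chlorophyll b synthesis gene CAO (0.57, SE 0.12, limma adjusted p = 0.0488), and 5 adjusted over the list alone (camera adjusted p = 0.0601). Rapid stress genes had a median of 1.85 with 0 called and 9 adjusted over the list alone (camera adjusted p = 7.8e-05, and adjusted p = 0.603 with an estimated correlation). The salicylic acid list had 2 called, CBP60G and PR1, a pathogenesis-related gene, and 9 adjusted over the list alone, with a median of 0.96, also with DLO1 at its bound (camera adjusted p = 9.76e-05, and adjusted p = 0.603 with an estimated correlation). PR1 rested on 2 reads in Ler and 95 in the double mutant, a ratio of 40.3 with a counting interval of 10.9 to 338. Jasmonate genes had a median of 0.68 and 0 called (camera adjusted p = 0.00123, and adjusted p = 0.603 with an estimated correlation), a call lost without Ler replicate 2 (camera adjusted p = 0.0681). Photosynthesis genes had a median of 0.26 and 0 called (camera adjusted p = 0.000278, and adjusted p = 0.603 with an estimated correlation). Clock genes had a median of 0.37 and 0 called, with 10 adjusted over the list alone (camera adjusted p = 0.00149, and adjusted p = 0.505 with an estimated correlation).

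Among the lists that camera did not call (adjusted p from 0.0601 to 0.996), IAA2 (1.1) and GH3.5 (1.71) were higher in the auxin list, and FUL (0.55) and SEP3, a MADS-box gene of organ identity (0.36), in the organ identity list. SPT (-0.59) and CRC, a YABBY gene of carpels and nectaries (-0.55), were lower in the carpel list, as were HSP90.1 (-0.81) and the chaperone gene FKBP65 (-0.64) among heat shock genes and SPL15, a gene that promotes flowering (-0.71), in the flowering time list. The meristem list had 0 of 25 called, with an unadjusted p = 0.000247 in the mixed test of fry. Pollen, flavonoid and cytokinin lists had 0 called. The mature pollen list, a sign of older tissue, had a median of 0.67 (camera adjusted p = 0.276). Relative to the mean of the 8 libraries, its median in replicates 1 and 2 was 0.74 and -0.12 in ag-10 fhy3-68 and 0.54 and -0.16 in fhy3-68. It was -0.21 and 0.14 in Ler and -0.35 and -0.25 in ag-10. A difference in flower age between these libraries was not tested. Adjusted over the list alone, 3 auxin, 5 light signalling, 2 organ identity and 1 pollen gene were higher, and 2 carpel, 2 heat shock, 1 organ identity, 1 flowering time and 1 light signalling gene were lower. The 2 late flower genes had a median of 0.16, with 1 higher adjusted over the list alone.

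With library totals, 890 genes were called, 423 higher and 467 lower, so the share called higher went from 57.3% to 47.5%. With the edgeR quasi-likelihood test, AT2G33830 (adjusted p = 0.052), BT2 (0.0528), SEN1 (0.0595), CAO (0.0531) and SEP3 (0.0528) were not called. Fits without a fhy3-68 library took the widest replicate difference out of the variance shared by all genotypes, which raises the count. The limma count was 2 without either Ler library, 483 and 489 without ag-10 replicates 1 and 2, 2802 without either fhy3-68 library, 22 without ag-10 fhy3-68 replicate 1 and 145 without ag-10 fhy3-68 replicate 2.

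The effect of fhy3-68 in the ag-10 background came from libraries that the comparison in Ler does not use. FHY1 fell from 19.4 ± 2.33 in ag-10 to 0.46 ± 0.311 in ag-10 fhy3-68, and ARC5 from 70.2 ± 8.58 to 8.18 ± 0.742 (SD, n = 2 each). In total 298 genes were called, 197 higher and 101 lower. Of these, 227 were called with the same sign in fhy3-68 against Ler, 156 higher and 71 lower, where independent lists of these sizes would share 4.46 and 0.794, and 0 were called with opposite signs. Both comparisons took their variance from all 8 libraries there. Fitted each on its own 4 libraries, they had 85 genes called with the same sign, 66 higher and 19 lower, against 5.09 and 0.261 for independent lists, and 0 with opposite signs. These chance values leave out that same-numbered libraries of fhy3-68 and ag-10 fhy3-68 deviated together (correlation across genes 0.45).

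The largest decreases were AT3G57930 (-4.63), FHY1 (-4.41), AT2G41990 (-3.61), ARC5 (-3.03), AT3G47010 (-2.79), AT2G40820 (-2.48), AT3G07580 (-2.38), ADT4 (-2.37), AT5G11930 (-2.25) and ALDH3H1 (-2.06), with limma adjusted p from 0.0101 to 0.0415. The largest increases were AT1G12010 (6.35), AT2G05540 (5.88), CEP1 (5.54), CEP2 (4.95), the nitrilase gene NIT2 (4.22), the homeodomain genes HB21 (4.15) and HB40 (3.84), NAC3 (3.53), AT5G39520 (3.51) and AT3G15450 (3.36), with limma adjusted p from 0.0101 to 0.0499. CEP1, CEP2, NIT2 and AT5G39520 rested on 3, 1, 2 and 3 reads in ag-10. Their ratios were 273 (counting interval 93.3 to 1330), 553 (99 to 21900), 175 (48.1 to 1450) and 65.5 (22.1 to 320). QQS was not called here, with a log2 fold change of -0.65 (SE 0.25, limma adjusted p = 0.196).

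Across the genes, the fold changes of fhy3-68 in the 2 backgrounds had a Pearson correlation of 0.83 and a Spearman correlation of 0.77, where genes are not independent replicates. Of the 449 genes called higher in fhy3-68 against Ler, 444 also lay higher in ag-10 fhy3-68 than in ag-10, with a median log2 fold change of 1.24 in Ler and 0.95 in ag-10. Of the 156 called lower, 154 lay lower there too, with medians of -0.75 and -0.67. These genes were chosen by their call in Ler, which enlarges their medians there. The smaller medians in ag-10 therefore do not show a weaker effect.

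**Figure D3:**
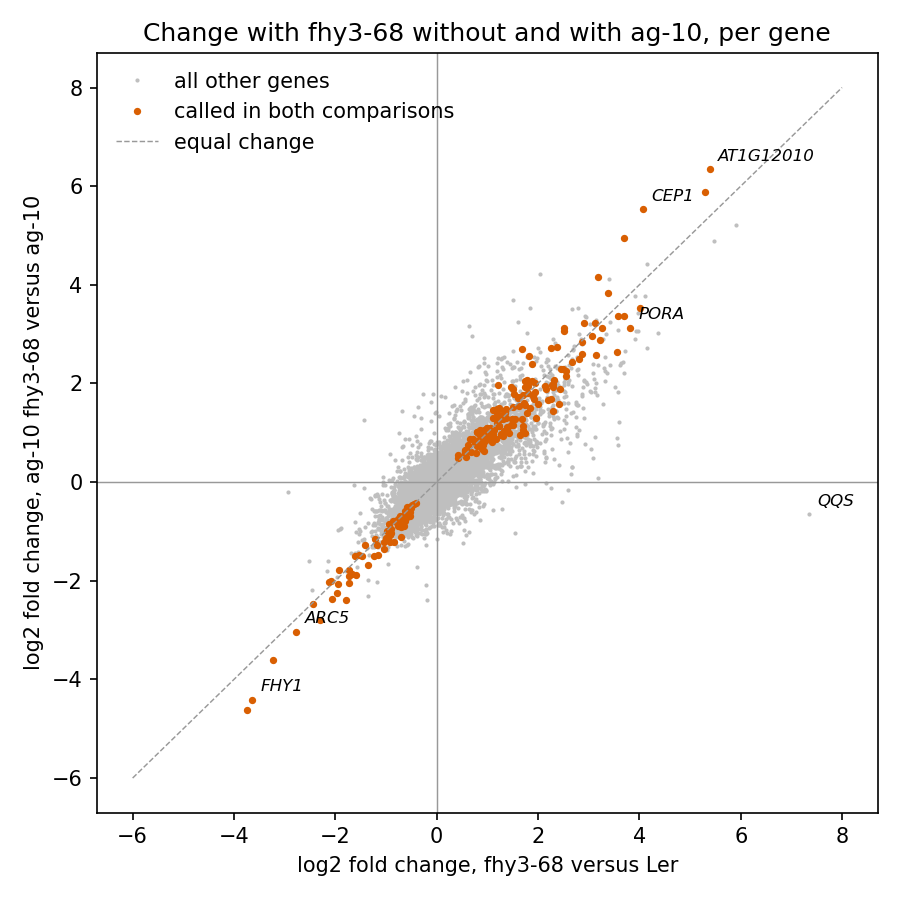
Log2 fold change of each gene with fhy3-68 in the Ler background (horizontal axis) and in the ag-10 background (vertical axis). The 227 genes called in both comparisons with the same sign are coloured and lie along the line of equal change, and QQS lies apart from it.

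Camera called 8 lists in the ag-10 background, but none with an estimated correlation (adjusted p from 0.465 to 0.682). Anther and tapetum genes had a median of -0.36, with A9 (-0.73) and CYP703A2 (-0.81) called and 9 lower adjusted over the list alone (camera adjusted p = 2.02e-06, and adjusted p = 0.465 with an estimated correlation). Cell division genes had a median of -0.52, with AUR1 called (-0.69) and 13 lower adjusted over the list alone (camera adjusted p = 2.22e-08, and adjusted p = 0.465 with an estimated correlation). Rapid stress genes had a median of 1.8, with 0 called and 10 adjusted over the list alone (camera adjusted p = 1.79e-05, and adjusted p = 0.557 with an estimated correlation). Jasmonate genes had a median of 0.73, with 0 called and 2 adjusted over the list alone (camera adjusted p = 0.00032, and adjusted p = 0.557 with an estimated correlation). Clock genes had a median of 0.34, with 0 called and 2 adjusted over the list alone (camera adjusted p = 0.000744, and adjusted p = 0.465 with an estimated correlation).

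Chlorophyll synthesis genes had PORA (3.13) and HEMA1 (0.56) called and a median of 0.13 (camera adjusted p = 0.044, and adjusted p = 0.465 with an estimated correlation). Leaving out ag-10 replicate 1 or ag-10 fhy3-68 replicate 2 kept that call, and each other removal ended it, with camera adjusted p from 0.0546 without either Ler library to 0.195 without ag-10 replicate 2 (0.0619 without either fhy3-68 library, 0.0977 without ag-10 fhy3-68 replicate 1). Photosynthesis genes had a median of 0.25 and 0 called (camera adjusted p = 5.5e-05, and adjusted p = 0.578 with an estimated correlation), lost without ag-10 replicate 2 (0.0764). Salicylic acid genes had a median of 0.67, 0 called and 2 adjusted over the list alone (camera adjusted p = 0.0346, and adjusted p = 0.682 with an estimated correlation). Their camera adjusted p was 0.458, with the opposite direction, without ag-10 replicate 1, 0.0521 without either fhy3-68 library and 0.266 without ag-10 fhy3-68 replicate 2. In lists that camera did not call (adjusted p from 0.0786 to 0.769), IAA2 (1.14), GH3.5 (1.71) and FUL (0.66) were higher and SPT (-0.7) was lower. The meristem list had 0 of 25 called and a median of -0.01 (camera adjusted p = 0.698, and unadjusted p = 6.02e-05 in the mixed test of fry). Mature pollen genes had a median of 0.72 and 0 called (camera adjusted p = 0.0951). Counts adjusted over the list alone gave 3 auxin, 3 light signalling, 1 organ identity and 1 pollen gene higher, and 2 organ identity, 2 flowering time, 2 heat shock, 1 carpel and 1 light signalling gene lower. The late flower genes had a median of 0.44, with 1 higher adjusted over the list alone.

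With library totals, 252 genes were called, 135 higher and 117 lower, so the share called higher went from 66.1% to 53.6%. CEP2 (adjusted p = 0.0584), NIT2 (0.0577), NAC3 (0.059), AT5G39520 (0.068), AT3G15450 (0.0523) and CYP703A2 (0.0521) were not called by the edgeR quasi-likelihood test. As above, fits without a fhy3-68 library drop the widest replicate difference from the shared variance, which raises the count. The limma count was 3 without either Ler library, 1 and 2 without ag-10 replicates 1 and 2, 1820 and 1810 without fhy3-68 replicates 1 and 2, and 10 and 65 without ag-10 fhy3-68 replicates 1 and 2.

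Between ag-10 fhy3-68 and fhy3-68, which differ by ag-10, limma called 0 genes. At an unadjusted p under 0.05 it found 427 genes, the edgeR quasi-likelihood test called 0, DESeq2 called 1 and the exact test of edgeR called 2. The median absolute log2 fold change over all genes was 0.09, against a median SE of 0.15, and 59 genes differed by at least 1. WUS had a log2 fold change of -0.27 (SE 0.15, limma adjusted p = 1) and SEP2 of 0.21 (SE 0.13, limma adjusted p = 1). The count stayed at 0 in each fit that left out a library.

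Camera called 5 lists as lower in the double mutant than in fhy3-68, but none with an estimated correlation (adjusted p = 0.374 for auxin and adjusted p = 0.733 for the other 4). They were jasmonate (median -0.4, adjusted p = 0.00118), auxin (-0.37, 0.00184), anther and tapetum (-0.18, 1.5e-05), rapid stress (-0.47, 0.0202) and cell division (-0.09, 0.0495). All 5 had 0 members called, and auxin had 1 lower adjusted over the list alone. With the replicate number as a block, cell division was no longer called (camera adjusted p = 0.078) and light signalling was called (camera adjusted p = 0.0401). Without ag-10 fhy3-68 replicate 1, the camera adjusted p was 0.642 for anther, 0.0744 for auxin, 0.874 for cell division and 0.686 for rapid stress, and without ag-10 fhy3-68 replicate 2 it was 0.0736 for jasmonate. Without fhy3-68 replicate 1 it was 0.964 for jasmonate, 0.42 for rapid stress and 0.981 for cell division, whose direction turned. Without fhy3-68 replicate 2 it was 0.123 for auxin and 0.209 for rapid stress. Cell division was also lost without either Ler library (0.064) and without either ag-10 library (0.0886). The other 14 tested lists had camera adjusted p from 0.168 to 0.65, and the late flower genes had a median of 0.09.

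The fold changes of ag-10 in the 2 backgrounds were barely related, with a Pearson correlation of 0.02 and a Spearman correlation of 0.06 across genes, and 0 genes were called in both (limma called 1 in Ler and 0 in fhy3-68). In the fhy3-68 background the median absolute log2 fold change (0.09) lay under the median SE (0.15). Noise alone could therefore bring the correlation near 0, and it does not show that ag-10 acts differently in the 2 backgrounds. The fold changes of ag-10 and fhy3-68 against Ler share the Ler libraries and had a Pearson correlation of 0.38, a Spearman correlation of 0.33 and a covariance of 0.046. In 100 simulations of unchanged libraries the mean Pearson correlation was 0.5, the mean covariance 0.0265 and the highest number of genes called in both 0. QQS was the 1 gene called in both, where independent lists would share 0.0226. Part of any excess may come from the shared Ler libraries, which are too few to split.

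The interaction asks whether the effect of fhy3-68 differs between the Ler and ag-10 backgrounds. It called 1 gene, QQS, with an interaction of -8 on the log2 scale (SE 0.35, limma adjusted p = 0.000776). QQS was higher than in Ler in each of the 3 mutant genotypes. At an unadjusted p under 0.05, limma found 241 genes. The edgeR quasi-likelihood test called 1 and DESeq2 called 3, as did limma without ag-10 replicate 1. The salicylic acid list had a median interaction of -0.69, with 18 of 21 members negative and 0 called (camera adjusted p = 9.73e-05, and adjusted p = 0.874 with an estimated correlation). That call was lost without ag-10 replicate 2 (0.14) and without fhy3-68 replicate 2 (0.0858). WUS (-0.15, SE 0.21), SEP2 (0.08, SE 0.18), FAR1 (0.11, SE 0.11), FHY3 (0.17, SE 0.18) and KNU (0.48, SE 0.42) had limma adjusted p = 1. The other 18 tested lists had camera adjusted p from 0.0795 to 0.971, and the late flower genes had a median of 0.37.

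Of the 32 list calls made by camera over the 6 contrasts, fry gave an unadjusted p under 0.05 for 16. In fhy3-68 against Ler these were all 8, from 0.000748 to 0.0485. In ag-10 they were 0 of 3, from 0.155 to 0.451. In the double mutant against Ler, anther, cell division and clock genes lay under 0.05, and photosynthesis (0.0768), rapid stress (0.0876), jasmonate (0.127) and salicylic acid (0.141) did not. Against ag-10, anther, cell division, chlorophyll and clock genes lay under it, and photosynthesis (0.0762), rapid stress (0.0826), jasmonate (0.108) and salicylic acid (0.429) did not. Against fhy3-68, auxin did (0.041), and the other 4 had p from 0.159 to 0.555. The salicylic acid list in the interaction had 0.362.

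Median, mean and camera direction of a list differed in sign in some cases, none of them called by camera. They were the clock and flavonoid lists in ag-10 and the flowering time list in fhy3-68. In the double mutant they were carpel, cytokinin, flowering time and light signalling against Ler, flowering time and light signalling against ag-10, and organ identity against fhy3-68. In the interaction they were anther, carpel, chlorophyll, flavonoid and organ identity.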

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

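The tests of the QQS pattern, and the comparisons with uncalled genes and with libraries left out in the last paragraph, were chosen after the results were seen, and the covariate tests of handling and time of day before their values were seen.

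QQS and the salicylic acid list stand here because a test of the interaction called them. The interaction was -8.00 on the log2 scale for QQS. For the salicylic acid list its median was -0.69, with 0 of 21 members called (camera adjusted p = 9.73e-05, and adjusted p = 0.874 with an estimated correlation). In the list, PR2 stood at 3.81 and 49.86 and PR5 at 6.28 and 70.23 in the 2 ag-10 libraries, and the list was not called without ag-10 replicate 2 (camera adjusted p = 0.14) or without fhy3-68 replicate 2 (0.0858).

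QQS stood at 0.14 and 0.32 in the Ler libraries and between 100.3 and 207.18 in the 6 mutant libraries. Beside QQS, 0 genes lay under 1 in both Ler libraries and at 10 or more in all 6 mutant libraries, or the reverse. That argues against Ler libraries from a stock with many such differences. It cannot tell against a closely related stock or mixed-up labels, since limma called only QQS between ag-10 and Ler. Of the 20 listed genes nearest to QQS, 1 had an unadjusted limma p under 0.05 in ag-10 against Ler, where chance gives 0.36. It was AT3G30393, at -1.31 in ag-10 and -1.05 in fhy3-68 (limma adjusted p = 0.154). In fhy3-68, BR6OX2 was called (-0.79, limma adjusted p = 0.044) and the other neighbours were not. Both genes were named after their values were seen. These counts cannot tell a segment with few or small changes from none. Also open is a difference at QQS itself, inherited or epigenetic, between this Ler stock and the line from which the mutants descend. Such a difference may not depend on ag-10 or fhy3-68. A direct effect of both mutations on QQS was not tested apart from it.

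Rapid stress genes (median 2.3 with 1 of 14 called, camera adjusted p = 7.68e-07, and adjusted p = 0.478 with an estimated correlation) and evening clock genes (median 0.76 with 0 of 9 called, camera p = 1.04e-05, and p = 0.154 with an estimated correlation) lay higher in fhy3-68, so harvest handling and time of day were weighed with a score per library as a covariate. For the genes called lower, the rapid stress score moved the median log2 fold change from -0.75 (median SE 0.13) to -0.71 (SE 0.24). Selection for small replicate differences limits that value (median residual SD 0.12, against 0.36 in uncalled genes). The median of uncalled genes of as large a fold went from -0.9 to -0.79. In each fit without 1 library, at least 95% was left for the called and 76% for the uncalled genes. The uncalled genes thus kept most of their median under this score. Their SE with the score was not computed, so the bound set beforehand could not be checked for them. The score did not overlap between Ler (-0.6 and -1.59) and fhy3-68 (1.34 and 1.38). It hardly varied within fhy3-68, so its slope rested on the other genotypes. These values therefore do not decide whether handling lowered these genes. For the genes called higher the rapid stress score moved 1.24 (SE 0.2) to 0.93 (SE 0.33) and the uncalled genes from 1.73 to 0.45. The bound set beforehand, which the called genes met, does not count there. The called genes had small replicate differences by selection (median residual SD 0.22, against 0.7 in the uncalled genes), which limits what a covariate can move. With the clock score the called medians were 1.07 (SE 0.25) and -0.72 (SE 0.18) and met the bound too. The uncalled higher genes went from 1.73 to 1, with 40% left without Ler replicate 2. The uncalled lower genes went from -0.9 to -0.75. Without either ag-10 library, whose scores of -0.87 and 0.66 lay farthest apart within a genotype, 21% was left. Without any 1 of the 6 other libraries, 76% to 86% was left. Time of day and handling, for both sets, therefore cannot be told apart from fhy3-68. The number of called genes fell from 605 to 1 with either covariate, as the SE grew and a residual degree of freedom was spent, so the calls did not hold.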

How the results depend on the processing

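Alternatives added after the data were seen are the edgeR quasi-likelihood test, pseudocounts of 0.1 and 1, a minimum mean of 5, the crossed block and the overlap on separate libraries. Counts are in the order ag-10, fhy3-68 and ag-10 fhy3-68 against Ler, then ag-10 fhy3-68 against ag-10 and against fhy3-68, then the interaction. They were 1, 605, 859, 298, 0 and 1 with limma, 1, 511, 755, 207, 0 and 1 with edgeR quasi-likelihood, 23, 1491, 1589, 1068, 1 and 3 with DESeq2, 27, 1962, 2158, 1490 and 2 with the exact test of edgeR, and 9, 345, 2917, 504 and 0 on the 4 libraries compared. The last 2 were not run for the interaction. A minimum absolute log2 fold change of 1 left 328, 382 and 187 of the 3 large counts and 135 of the 227 genes shared by the 2 fhy3-68 comparisons, which shared 85 when each was fitted on its own 4 libraries. Pseudocount 0.1 called 2 genes in ag-10. The other counts under RLE size factors, library totals, pseudocounts and minimum levels stayed within 1.5 times. A table with no filter could not be made from values filtered before deposit, and with 0 organelle genes none could be left out. The cause of these differences was not tested.

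Left out in turn, single libraries moved the counts between 1 and 4, 1 and 3399, 2 and 2802, 1 and 1820, 0 and 0, and 1 and 3. The numbers of lists called by camera, 3, 8, 7, 8, 5 and 1, moved between 2 and 6, 8 and 10, 7 and 10, 7 and 10, 3 and 9, and 1 and 7. All 6 were 0 with an estimated correlation, and library totals called 3 lists in the interaction. These losses do not all mark genes that move together. In fhy3-68 against Ler the auxin and clock lists had estimated correlations of -0.006 and 0.04, near the preset 0.01. Without 1 fhy3-68 library, the replicate difference of that genotype, the largest of the 4, left the shared variance. The highest gene counts therefore do not show effects that a library had hidden.

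Of 109 calls of named genes, 94 held with the edgeR quasi-likelihood test and 108 with DESeq2, 4 held in all 8 fits that left out a library, and 0 changed sign in these. Of the 27 comparisons of study genes that limma did not call, DESeq2 called 2, both of SEP2. In the fits that left out a library, 3 of the 32 called lists turned direction: heat shock in ag-10, salicylic acid in ag-10 fhy3-68 against ag-10, and cell division in ag-10 fhy3-68 against fhy3-68. Among named genes, a sign changed there only for study genes that were not called. FHY3 lay between -0.08 and 0.00 in ag-10, between -0.07 and 0.33 for ag-10 fhy3-68 against fhy3-68 and between -0.03 and 0.37 in the interaction. KNU lay between -0.61 and 0.00 in ag-10, -0.30 and 0.07 in fhy3-68, and -0.13 and 0.24 in ag-10 fhy3-68, all against Ler. SEP2 lay between -0.06 and 0.22 in the interaction, and at -0.04 without ag-10 replicate 1.

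Replicate numbers did not pair the libraries of all 4 genotypes: deviations of same-numbered libraries had correlations of 0.02, 0.07 and -0.11 between Ler and the mutants, but 0.17, 0.28 and 0.45 among the mutants. The second principal component (14% of the variance) lay at 28.43 and 25.12 in replicate 1 and at -23.36 and -14.56 in replicate 2 of fhy3-68 and ag-10 fhy3-68, so a replicate effect shared by mutant libraries is not excluded. With the replicate block, limma called 1, 1849, 1959, 927, 0 and 1 genes, and 109 of 109 named calls held. The block also called SEP2 in fhy3-68 (limma adjusted p = 0.0406) and WUS in ag-10 fhy3-68 (0.0325), both against Ler. Of the list calls, it ended that of cell division in ag-10 fhy3-68 against fhy3-68 (camera adjusted p = 0.078). It added light signalling there (0.0401), flavonoids in ag-10 fhy3-68 against ag-10 (0.0149), and auxin (0.033) and light signalling (0.0404) in the interaction, where 3 lists were then called. Crossing the Ler numbers gave 1488 genes for ag-10 fhy3-68 against Ler, beside 859 without a block. Calls gained under the block against Ler therefore do not show that the numbers pair there.

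KNU, at 25 to 40 reads per genotype, had an SE of 0.3 in each comparison of 2 genotypes, and what depth added to it was not tested. In the simulation of fhy3-68 against Ler, which gave all genotypes the same spread, 56% of genes changed 2-fold were recovered.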

Other observations

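The lists of dark and starvation genes, senescence and dormancy genes, and morning and evening clock genes were composed after the first results were seen, and the tests that use them were chosen then. The test of the region around FHY3 was set before its result was seen.

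Some of the largest increases in fhy3-68 were genes known to be induced by darkness and sugar starvation, and a list of such genes was composed around them. All 18 measured members lay above Ler, with a median log2 fold change of 1.8 (camera p = 4.46e-10, and p = 0.105 with an estimated correlation). Limma called 5 of them: BT2 (5.9), AT2G33830 (5.47), DIN10, a raffinose synthase family gene (3.97), PHI-1 (2.75) and the trehalose phosphate synthase gene TPS8 (2.15). In ag-10 fhy3-68 the median was 1.41 (camera p = 2.89e-10, and p = 0.103 with an estimated correlation). There 9 were called, among them ASN1, an asparagine synthetase gene induced in the dark (4.25, limma adjusted p = 0.0401), and SEN1 (4.72, limma adjusted p = 0.0444). In ag-10 the median was 0.09, and limma called 0 of the 18. Genes that were seen first are members of this list and of the next. The fhy3-68 medians and camera p of both therefore partly restate what prompted them. Genes of senescence and bud dormancy had a median of 2.37 in fhy3-68 (camera p = 1.18e-08, and p = 0.0527 with an estimated correlation). Of these 16, limma called 5: NAC3 (4.02), the homeodomain genes HB40 (3.38) and HB21 (3.18), the senescence regulator NAP (2.91) and RD26 (2.41). In ag-10 fhy3-68 their median was 2.16 with 7 called (camera p = 2.63e-09, and p = 0.0466 with an estimated correlation). BRC1, which holds axillary buds dormant, stood at 2.34 (SE 0.59, limma adjusted p = 0.0732) and HB53, a partner of HB21 and HB40, at 1.69 (SE 0.4, limma adjusted p = 0.0643) in fhy3-68. Limma called HB53 in ag-10 fhy3-68 (2.07, adjusted p = 0.0401).

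The 9 evening clock genes all lay above Ler in fhy3-68, with a median of 0.76 (camera p = 1.04e-05, and p = 0.154 with an estimated correlation), while the 7 morning genes had a median of -0.28 (camera p = 0.291). In ag-10 the evening genes also all lay above Ler, with a median of 0.39 (camera p = 5.67e-05, and p = 0.184 with an estimated correlation). None of the 16 was called by limma in either mutant. PRR5, a pseudo-response regulator of the clock, had a log2 fold change of 2.36 (SE 0.53, limma adjusted p = 0.0594). The evening minus morning score was -0.87 and -0.61 in Ler, -0.87 and 0.66 in ag-10, 0.27 and 0.63 in fhy3-68, and 0.04 and 0.74 in ag-10 fhy3-68, so the ag-10 libraries differed as much as the genotypes did.

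A hypothesis from the largest increases is that young inflorescences of fhy3-68 may carry a transcript state like that of darkness or sugar starvation. To look beyond the genes that had prompted it, the 12 members of the dark and starvation list whose values had not been seen were taken alone. Their median was 0.9 in fhy3-68 and all 12 lay higher (camera p = 1.7e-06, and p = 0.096 with an estimated correlation). The 12 unseen members of the senescence and dormancy list had a median of 1.79, with 11 higher (camera p = 1.97e-05, and p = 0.049 with an estimated correlation), among 24 such tests that were not adjusted. At the preset correlation the result goes the way the hypothesis predicts. It is no independent test, because the unseen members were measured in the same libraries and may move together with the seen ones. The harvest time and light conditions of the libraries are not given in the sources used here. The time of day, which also moves these genes, was not separated from the genotype. Nor was the rise of the rapid stress, jasmonate and salicylic acid lists in the same libraries.

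A segment inherited with the fhy3-68 mutation could change genes near FHY3 whatever FHY3 does. Among the 100 listed genes nearest to FHY3, 4 were called in fhy3-68 against Ler, where chance gives 3.05 (one-sided Fisher exact p = 0.364). They were BBX31 (-2.14), named above by rule, and AT3G21480 (-0.47), AT3G21790 (0.84) and CWLP (0.92), named after their values were seen. The count is too small to tell a small segment from none.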
